A study of Gallus gallus with 4 samples.

How the data were processed

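Tracheal RNA of chickens was compared on 4 cDNA arrays with 2 dyes each. The infected RNA came from tracheas 3 days after inoculation with the Massachusetts strain of infectious bronchitis virus, a coronavirus of chickens. The control RNA came from tracheas 3 days after sterile water was given. Both RNAs were placed on every array, so each array is a direct comparison and there is no common reference. Per the labels, the infected RNA was in Cy5 on slides 1 and 2 and in Cy3 on slides 3 and 4. RNA was amplified, reverse transcribed and coupled to the dyes, per the labels' protocols. The protocols of slides 2, 3 and 4 say that RNA came from pooled samples, and that of slide 1 lacks this word. The labels do not say whether the 4 arrays carried separate pools. The p-values therefore measure only the spread between these hybridisations, which may be technical.

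The values used were the deposited log2 ratios, 1 column per array and 15769 probes each. The image analysis, the background correction and any normalization are not given in the sources used here. The scale was read from the values. The array medians over the clone probes were -0.59, -0.54, -0.83 and -0.11 for slides 1 to 4, so the columns had not been centred. The largest value was 16.61, the log2 of 100000, and 119 entries stood at it. A further 2295 entries were missing. Spot intensities were not used here, so no correction for spot brightness (loess) was run and the signal over background of a ratio is unknown. Between 3.86% and 5.85% of the ratios on an array equalled, to 3 decimals, the log2 of a ratio of whole numbers up to 10. At slightly shifted values the same count gave 1.14% to 1.53%.

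The direction of the ratio stays unknown. The columns of opposite dye orientation correlated negatively in all 4 pairs, so the columns are still ratios of 1 dye over the other and had not been turned to infected over control. Neither the labels nor the values say which dye is the numerator. Each slide title lists the Cy3 RNA before the Cy5 RNA, but does not say that this is the order of the ratio. Each change is therefore given as a size and a side. The Cy3 side holds the probes whose ratio was higher on the arrays with the infected RNA in Cy3, and the Cy5 side those higher with the infected RNA in Cy5. If the ratio is Cy5 over Cy3, the Cy3 side is lower in infected trachea and the Cy5 side higher. If it is Cy3 over Cy5, both statements are exchanged.

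Entries at the largest value were set to missing, and each array was centred on the median of its clone probes. The plan fixed before the data were examined was to use deposited values if they were normalized. The centring was chosen after the medians were seen and before any calls were compared, and uncentred values became an alternative. The handling of the capped entries was also chosen after the values were seen. Both choices move the count of calls by over 1.5 times: 98 probes were called as reported, 401 without centring and 30 with capped entries kept. The 160 control spots were left out. They comprise 128 spots with the names of 4 plant genes, 32 copies each, and 32 spots of chicken genomic DNA.

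Each clone probe was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). The model held a dye term and a treatment term coded by the dye of the infected RNA. A probe needed values on at least 3 of the 4 arrays, which 15127 of the 15609 clone probes had. The test was two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all tested probes, with a threshold of 0.05. The size given for a probe is its treatment term, and the SE is limma's moderated one, with the dye term removed. The SD is that of the turned ratios, whose sign was reversed on the arrays with the infected RNA in Cy3. It still holds the dye effect, so the SE does not follow from the SD. A probe with 3 arrays has 1 array in one of the orientations, and its residual spread comes from the other orientation alone. A called probe is termed mirrored if its mean ratios in the 2 orientations had opposite signs and the smaller was at least 0.5 of the larger. This description was added after the values were seen. The steps were tested on simulated data with 15127 probes and 200 changed ones. Calls recovered 0% of probes changed by 1 on the log2 scale, 70% of those changed by 2, and 98% of those changed by 3 or by 4. Among unchanged probes 9 were called, and with no changed probe 1 was called. The simulated noise was normal and independent between arrays, with the spread fitted by limma. With no changed probe, 5.02% of simulated probes had an unadjusted p under 0.05 in limma. On the real arrays 19.6% of the plant-named control spots did. The simulated rates of recovery and of false calls therefore may not hold for the real arrays.

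The probe identifiers are clone or plate positions, and 0 of them equal a symbol, synonym or locus tag of the gene table used here. Tests of genes and of the gene lists fixed in advance were therefore not run. The rule for named items, fixed before the data were examined, then allows 2 probe identifiers per side. They are those with the largest change among called probes with the same direction on every measured array. The 3 identifiers with the prefix PEN were chosen after their values were seen. Clone sets are the groups of probes that share an identifier prefix. The labels do not say what the prefixes stand for. Sides were compared between clone sets by Fisher's exact test on probes with an unadjusted p under 0.01. These comparisons were chosen after the counts per set and side were seen.

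Centred and uncentred values were both fixed before the data were examined, centred ones as the alternative, and their roles were exchanged after the medians were seen. The other alternatives fixed before the data were examined were arrays scaled to 1 common spread, no dye term, values on all 4 arrays, no filter, a robust prior, a minimum of 1.5-fold, Spearman correlation, and leaving out each array. The scaling used limma's normalizeMedianAbsValues, because the planned function could not be run on centred values. Alternatives chosen after seeing the data were capped entries kept, each clone set centred on its own median, and whole-number ratios left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.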

Results

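The arrays addressed which transcripts of the chicken trachea differ 3 days after inoculation with the Massachusetts strain of infectious bronchitis virus, compared with tracheas given sterile water. There were 4 arrays, 2 in each dye orientation, and their small number limits the precision of every value. Slides 1 to 4 measured 14756, 15070, 15458 and 15378 probes. Genes are not named, because the probes carry clone positions. Whether a change is a rise or a fall in infected trachea is open, because the numerator of the deposited ratio is unstated. Sizes are therefore given with the dye orientation in which the ratio was higher, as the Cy3 side or the Cy5 side.

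Between infected and control trachea, 98 of 15127 tested clone probes (0.648%) differed at an adjusted p under 0.05 in limma. The Cy3 side held 86 of them and the Cy5 side 12, a Cy3 share of 87.8% (exact 95% interval 79.6% to 93.5%, which treats probes as independent). The median change of the called probes was 2.53 on the log2 scale, or 5.79-fold, with a range of 1.48 to 5.13. All 98 changed by at least 2-fold, 69 by at least 4-fold and 22 by at least 8-fold. Cy3-side calls had a median size of 2.57 on the log2 scale and Cy5-side calls 2.38. If the ratio is Cy5 over Cy3, most called probes were lower in infected trachea, and if it is Cy3 over Cy5, most were higher.

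No probe was called with slide 3 or with slide 4 left out, where 1263 and 2248 probes had an unadjusted p under 0.05 in limma. With slide 1 left out 623 probes were called, and with slide 2 left out 441. In such a fit the residual spread comes only from the orientation that keeps 2 arrays, so these counts do not show which slides carry the change. Uncentred values gave 401 calls, the model with no dye term 14, capped entries kept 30, a robust prior 169 and whole-number ratios left out 296.

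Of the 98 called probes, 75 were measured on all 4 arrays, 70 on the Cy3 side and 5 on the Cy5 side. Among these, 51 were mirrored, 49 of them on the Cy3 side and 2 on the Cy5 side. Their changes had opposite signs in the 2 dye orientations, but the smaller could be as low as 0.5 of the larger. The other 23 called probes were measured on 3 arrays. Among the tested probes 13843 had values on all 4 arrays and 1284 on 3, so probes with 3 arrays were called more often. In all 23 the larger change lay in the orientation with 1 array. For 22 of them, which were not mirrored, a single spot therefore carried most of the call. The exception, C0004118_M24, was mirrored and was picked out after its values were seen, with ratios of 2.21 and 2.35 on slides 1 and 2 and -2.48 on slide 4. In 23 called probes, 16 of them measured on 3 arrays, the mean ratio in one orientation was under 10% of that in the other. In 22 of these the larger change was on slide 1, slide 2 or both.

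**Figure D1:**
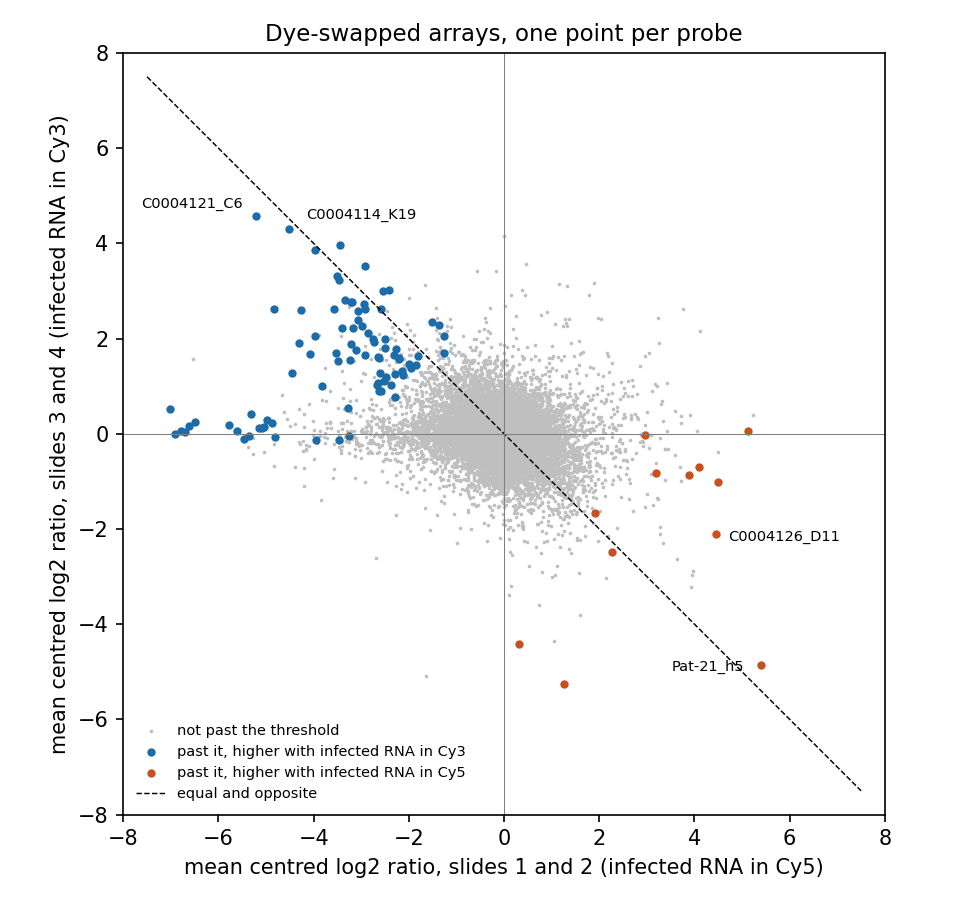
Each point is a tested clone probe, placed by its mean centred log2 ratio on slides 1 and 2 (x axis) and on slides 3 and 4 (y axis). The dashed line marks equal and opposite change. The 86 Cy3-side calls (blue) and 12 Cy5-side calls (orange) include 52 mirrored probes. These have means of opposite sign, the smaller at least 0.5 of the larger. The calls also include 23 probes whose mean in one orientation was under 10% of the other.

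The largest change was that of probe Pat-21_h5, at 5.13 ± 0.32 on the log2 scale (SD, n = 4; SE 0.18), or 35.0-fold, with an adjusted p of 0.0040 in limma. It was on the Cy5 side on 4 of 4 arrays, with centred log2 ratios of 5.41, 5.39, -4.94 and -4.78 on slides 1 to 4. Probe C0004126_D11 was also on the Cy5 side, at 3.28 (SE 0.28, n = 3), or 9.72-fold, with an adjusted p of 0.040 in limma. With no dye term its size was 2.89, and the SD of its turned ratios was 1.40. Its values were 4.45 on slide 2, -1.75 on slide 3 and -2.48 on slide 4, so it was not mirrored and its largest value is a single spot. Its deposited ratio was -2.585 on both slides 3 and 4, a ratio of small whole numbers, so its residual spread comes from the centring. On the Cy3 side, probe C0004121_C6 changed by 4.90 ± 1.30 (SD, n = 4; SE 0.49), or 29.8-fold, with an adjusted p of 0.038. Its ratios were -3.70, -6.75, 4.55 and 4.61 on slides 1 to 4, and its change was 5.66 on the log2 scale without slide 1 and 4.14 without slide 2. Probe C0004114_K19 changed by 4.41 ± 0.22 (SD, n = 4; SE 0.19), or 21.2-fold, with an adjusted p of 0.0064 and ratios of -4.43, -4.59, 4.10 and 4.52. The calls of Pat-21_h5, C0004121_C6 and C0004114_K19 ended with slide 3 or with slide 4 left out, at adjusted p of 0.15, 0.31 and 0.15 without slide 3 and 0.18 for each without slide 4. Their sizes were 5.09, 4.91 and 4.51 on the log2 scale without slide 3, and 5.17, 4.88 and 4.30 without slide 4. C0004121_C6 also missed the threshold with capped entries kept (adjusted p of 0.053). C0004126_D11, which lacked the arrays to be tested without slide 2, 3 or 4, with values required on all 4 arrays or with whole-number ratios left out, missed it with scaled arrays (0.073), with no dye term (0.16) and with capped entries kept (0.062).

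The identifiers PEN_c-rel and PEN_mtd, chosen after their values were seen, did not pass the threshold. PEN_c-rel was on the Cy5 side at 0.46 ± 0.32 on the log2 scale (SD, n = 4; SE 0.21), with an adjusted p of 0.29. PEN_mtd lay at 0.09 on the Cy3 side, with an adjusted p of 0.80. PEN_TF-10 was measured on slides 3 and 4 alone and was not tested.

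The called probes came from 4 clone sets. The set C0004 held 69 of them among 11017 tested, Pat 19 among 1965, DT40subNB 8 among 1769 and DKFZ426 2 among 374. The called share did not differ from that of the other probes for any of these sets by Fisher's exact test (adjusted p of 0.76, 0.28, 0.69 and 1, over 4 comparisons). The side did differ. Of the probes with an unadjusted p under 0.01, Pat had 128 on the Cy3 side and 17 on the Cy5 side (88.3%), and C0004 had 506 and 303 (62.5%; Fisher's exact test, adjusted p = 4.0e-10). DKFZ426 had 24 and 2 (92.3%; adjusted p = 0.0021 against C0004). DT40subNB had 52 and 22 (70.3%; adjusted p = 0.21). Without slide 4, C0004 had 187 on the Cy3 side and 266 on the Cy5 side (41.3%), so its side turned, and Pat had 76 and 22 (77.6%). The odds ratio of Pat against C0004 was 4.50, and it fell to 1.96 without slide 2 (84.2% against 73.0%, Fisher's exact p = 0.0075) and to 1.96 with each clone set centred (79.4% against 66.3%, Fisher's exact p = 0.0024). Clones of 1 transcript are not independent, and such copies were not identified here. An unadjusted p under 0.01 in limma was also found for 8 of 102 plant-named control spots, against 6.97% of clone probes. Passing it therefore does not by itself mark a response to infection.

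**Figure D2:**
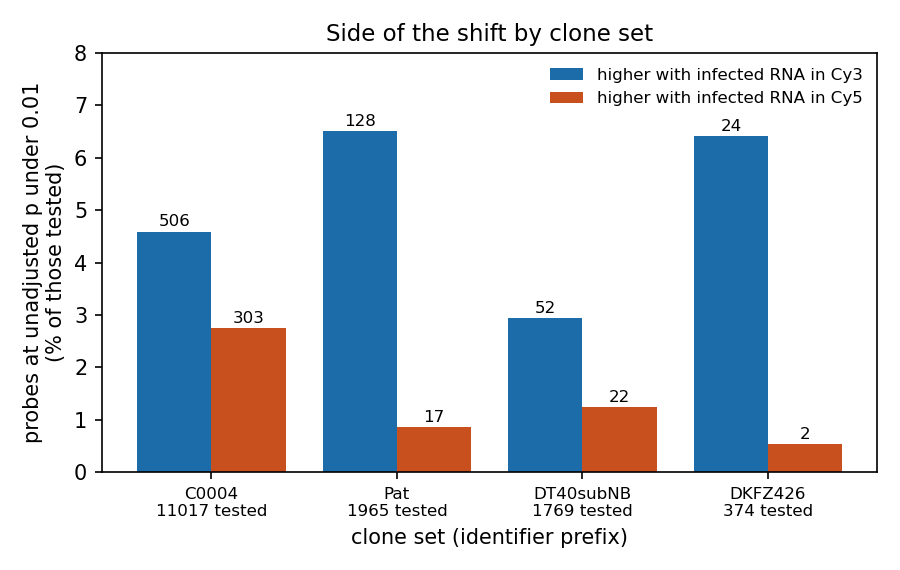
Bars give the share of tested probes with an unadjusted p under 0.01 in each clone set (percent of probes tested), by side, with the number of probes above each bar. Pat has 128 probes on the Cy3 side (blue) and 17 on the Cy5 side (orange), and C0004 has 506 and 303.

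With the called probes included, 3060 of the 15127 had an unadjusted p under 0.05, where 756 are expected by chance, with 1751 on the Cy3 side and 1309 on the Cy5 side. At an unadjusted p under 0.01 in limma the Cy3 side held 710 of 1054 probes (67.4%). Its share was 69.3%, 74.6% and 66.3% without slide 1, 2 or 3, and 50.2% without slide 4. At an adjusted p under 0.10 there were 449, 354 and 95 on these sides. Among the 13843 probes measured on all arrays, the 2 orientations did not overlap for 7580 (54.8%), where chance gives 33.3%. The control spots with plant gene names gave a similar share of small p-values. These spots are copies of 4 genes, and the interval treats them as independent. Of 102 tested, 20 (19.6%, exact 95% interval 12.4% to 28.6%) had an unadjusted p under 0.05, against 20.2% of clone probes, with 11 on the Cy3 side and 9 on the Cy5 side. By gene, the share was 11.5% to 29.6%, and the side differed. On the Cy3 and Cy5 sides Cab had 3 and 0 such spots, NAC1 4 and 4, PRKase 0 and 4, and RUBISCO 4 and 1. The smallest p of a plant spot was 0.000339, in a limma fit that held the control spots as well, and the largest p among called probes was 0.000318. Since only 0.648% of clone probes were called, 102 spots are too few to test that threshold. Plant spots changed by at least 1 on the log2 scale in 17.6% of cases, against 8.23% of clone probes, and by at most 2.36. Of 31 tested spots of chicken genomic DNA, 10 (32.3%) had an unadjusted p under 0.05, 2 on the Cy3 side and 8 on the Cy5 side.

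The dye term, which measures a ratio that stays the same when the RNAs change dyes, was called for 0 probes in limma. It had an unadjusted p under 0.05 for 1825 probes, where 756 are expected by chance. The 0 does not show that the called probes were free of a dye effect. Where the mean of a called probe in one orientation was near 0, its dye term was about as large as its treatment term. Examples are C0004124_L13 (dye -2.70, treatment -2.66) and C0004108_L6 (dye 2.59, treatment 2.52). Without centring the dye term was called for 635 probes. Across probes, the centred ratios of arrays of the same orientation correlated at a Pearson r of 0.425 (slides 1 and 2) and 0.357 (slides 3 and 4). Arrays of opposite orientation correlated at -0.219 (slides 1 and 3), -0.0891 (slides 1 and 4), -0.243 (slides 2 and 3) and -0.207 (slides 2 and 4). Probes are not independent replicates, so no p is given for these correlations.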

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

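Keeping capped entries, centring each clone set and leaving out whole-number ratios were tests chosen after the data were seen, and uncentred values took the place of centred ones as an alternative then. Counts of called probes are given in the order total, Cy3 side, Cy5 side, beside 98, 86 and 12 as reported. Uncentred values gave 401, 327 and 74, with 635 probes called for the dye term. Arrays scaled to a common spread gave 73 in total, and 6 on the Cy5 side. The model with no dye term gave 14, 13 and 1, the robust prior 169, 145 and 24, and capped entries kept 30, 23 and 7 with 18 for the dye term. Whole-number ratios left out gave 296, 258 and 38, with 2 for the dye term. Without 1 of the arrays the counts ranged from 0 to 623, 0 to 498 and 0 to 125, and those of the dye term from 0 to 232. The counts of 0 came with replicate 3 or replicate 4 (slides 3 and 4) left out, where limma gave 1263 and 2248 probes at an unadjusted p under 0.05. With 1 array left out, the residual spread of a probe comes only from the orientation that keeps 2 arrays. That is slides 1 and 2 without slide 3 or 4, and slides 3 and 4 without slide 1 or 2. The counts without 1 array therefore also depend on the spread of that pair, and do not show which slides carry the change. Beyond this, the cause was not tested for any of the moves in count. The other alternatives stayed within 1.5 times of the reported total. In each alternative, every called probe that could still be tested kept its side. The call itself was kept by 98 probes with uncentred values and by 14 with capped entries kept. For the named probes, 37 of the values under alternatives stayed past the threshold and 10 did not, with none on the other side. Both mean correlations between arrays moved by less than their spread. Gene-level tests, gene lists, the median over probes of a gene, genes with 1 probe, and both other set tests were not run, because the probes have no gene names here. No separate paired analysis was run, because each ratio already compares the 2 RNAs on 1 array. The signal over background is unknown, so its limit on single ratios cannot be stated.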

Other observations

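The tests of the centring and of noise in one orientation for the imbalance between sides, and the comparison of sides between clone sets, were chosen after the result was seen. The tests of an offset and of noise for the Pat set were chosen after its lean was seen and before their own results were. Slide 4 had the smallest spread of ratios, a median absolute deviation of 0.41 on the log2 scale against 0.62, 0.70 and 0.67 on slides 1 to 3. Its Dixon ratio of 0.719 was under the critical value, which is hard to reach with 4 values and does not show that the arrays were alike.

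Most called probes lay on the Cy3 side (86 of 98). The lowest share over 3 other centrings or scalings was 81.5%. That test could hardly have come out otherwise, so no conclusion is drawn from the share. The deposited array medians moved the treatment term by only -0.046 on the log2 scale, against a smallest called change of 1.48. These values show only that the centring did not set the side of the 98 calls. Leaving out the calls that were not mirrored left 94.2% of 52 on the Cy3 side (exact 95% interval 84.1% to 98.8%). The lean was therefore not confined to calls with a change in one orientation. Most mirrored calls were nevertheless also larger on slides 1 and 2, as the mirror rule allows. Noise in arrays of one orientation can thus have affected which probes were called, and it stays open as a cause. Of the 46 calls not mirrored, 95.7% were larger on slides 1 and 2. The lean was weaker at an unadjusted p under 0.01 in limma, at 60.7% of the mirrored probes that were not called. Among all probes at that p, called or not, the Cy3 share was 50.2% without slide 4. It was 69.3%, 74.6% and 66.3% without slide 1, 2 or 3. A shift that any spotted DNA shows cannot be told apart from a response to infection for the excess of small p-values, since 19.6% of plant-named spots had an unadjusted p under 0.05 in limma. The plant genes did not share a side (Cab 3 on the Cy3 side and 0 on the Cy5 side, PRKase 0 and 4). These spots therefore bear on the excess and not on the lean to the Cy3 side. Infection itself and a difference in makeup between the RNA pools remain untested.

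The probes of the Pat set leaned further to the Cy3 side than those of C0004, at 88.3% against 62.5% (odds ratio 4.50, exact 95% interval 2.64 to 8.13). With each clone set centred the Pat share was 79.4% against 66.3% (odds ratio 1.96, 1.24 to 3.19), so an offset of the whole set may account for part of the lean and the test argues against it as the whole cause. Among mirrored probes the Pat share was 92.4% against 53.0% for C0004 (odds ratio 10.7), which argues against noise in one orientation. The Pat share stayed above that of C0004 with each array left out, with the smallest odds ratio (1.96) without slide 2, but C0004 itself did not lean to the Cy3 side without slide 4 (41.3%). A response shared by the clones of this set is a candidate explanation, and repeated clones of a few transcripts stay open, since neither was tested.

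The 4 arrays can be split into 2 and 2 in 3 ways, and 1 of the 3 splits, the split by dye orientation, gave as many as 98 calls. The highest of the others was 0 calls in limma, with 189 and 205 probes at an unadjusted p under 0.05. Both counts are below the 756 expected by chance. In these other splits the difference between dye orientations enters the residual spread, so few calls were likely in any case. No conclusion is drawn from their counts. With 3 splits the share cannot fall under 33.3%, so they are too few for a share under 0.05.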
